A study of Mus musculus with 6 samples.

How the data were processed

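The series profiled 3 mouse epiblast stem cell (EpiSC) lines with 2 assays, giving 6 libraries. EpiSCs are pluripotent cells derived from the epiblast of the embryo after implantation. Lines 1, 2 and 3 are FT 8.73, FT 3.83 and FT 9.73 in the labels. DNA methylation was profiled at passages 15, 24 and 11, and RNA at passages 19, 14 and 15, so the 2 assays of a line came from different passages. The cells were grown without serum in the medium, with FGF2 and Activin A, per the labels' protocols. The embryonic stem cell data of the study belong to other series and were not analysed here.

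For methylation, sonicated DNA was captured on beads carrying the methyl-binding domain of MeCP2, washed, and released with rising salt (MethylCap-seq), per the labels' protocols. The protocol describes 2 eluates, and the labels do not say which of them entered each library. Capture followed by high-salt release favours fragments with many methylated CpGs, so the signal depends on CpG density as well as on methylation. It gives no methylation level per CpG. For RNA, poly(A) RNA was fragmented and primed with random hexamers, with no step that marks the strand, per the labels' protocols. Reads were 36 bases long, per the labels' protocols. The build was mm9, per the submitters' processing notes; the aligner is not given in the sources used here.

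The deposited files list 1 mapped read per line, with no header. In the MethylCap files each line spans 300 bases, the fragment length in the protocol, so the authors extended the reads; no start and strand occurs more than 2 times. In the RNA files each line spans 36 bases without a gap, so reads across splice junctions were not in the files used, and repeated starts were kept. All 3 MethylCap files hold 7139891 reads and all 3 RNA files hold 44903007 reads. Equal totals show that the depth was equalised before deposit, and no label or header says how. One RNA read ends at position 95272652 of chromosome 17, next to the end of that chromosome in mm9, so coordinates can be off by a base or so. The files hold no mitochondrial reads. A further MethylCap column holds 0 or 1, with no explanation, and entered no comparison.

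Reads were counted in 5-kb windows, at the middle of the fragment for MethylCap and of the read for RNA. MethylCap reads were counted once per start and strand, which left 7100473, 7129399 and 7124556 reads in lines 1, 2 and 3. All RNA reads were counted; 70.9%, 63.8% and 58.1% of them repeated the start and strand of another read in lines 1, 2 and 3. Counts were divided by the library total, giving RPM, the read count scaled to a common library size, in which 1 RPM of an RNA library is 44.9 reads. Logarithms used log2(RPM + 0.1) for MethylCap and log2(RPM + 1) for RNA, so that a fold difference of a low window is understated. A window was called methylated where its count exceeded the library mean by a one-sided Poisson test, at a Benjamini-Hochberg adjusted p under 0.01. This call compares a window with the same library and measures enrichment, not a methylation level. An RNA window was called expressed at 1 RPM or more in each of the 3 lines.

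No annotation or sequence of mm9 was used here. The gene-level plan was therefore replaced, by the rule fixed before the data were examined, with 5-kb windows named by coordinates, and no gene was named. The tests of marker gene lists, for expression and for promoter methylation, were not run. Regions named for MethylCap are the 5 per line that differ most from the nearer of the other lines, with adjacent windows joined, and the 5 windows with the highest mean RPM are named in each assay. RNA regions that differ between lines were named by the same measure, but that choice was made after their values were seen.

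Agreement between lines was measured by Spearman's rho and Pearson's r across windows, which are not independent replicates. Windows that differ between lines lay at least 4-fold above or below both other lines, with at least 20 MethylCap reads or 10 RNA RPM in the highest line. With 1 library per line and assay there is no test for a single window. The line number ties the 2 assays, because libraries with the same number come from the same cell line; the pairing was tested exactly over its 6 arrangements. Shares of reads carry Wilson 95% intervals, and ratios of 2 read counts exact 95% binomial intervals. Where a line had 0 reads, the fold was computed with a floor of 3 reads for that library. The floor leaves out the counting error of the other line's count, so these folds are not lower limits. Intervals cover counting error only, since PCR copies are not independent molecules.

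Chromosome doses were compared after matching windows on signal, in 20 bins, because line 1 had a more uneven signal than the other lines; the 0.1% of windows with the most reads were left out. RNA of a chromosome was compared by the median log2 ratio of its expressed windows. These 2 measures were chosen after the data were seen.

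The procedures were tested on simulated data. Counting noise alone put 20 of 502265 MethylCap windows and 0 of 238564 RNA windows past the 4-fold rule. Of 200 MethylCap windows raised 4-fold, 8-fold and 16-fold, 28.5%, 99.5% and 100% were recovered. For RNA the shares were 2%, 100% and 100%. The raised windows were drawn from a limited range of mean signal in each assay, with counting noise only. The shares therefore do not cover windows with lower signal. A flat genome gave 0 methylated windows. When 200 of its windows were raised 2-fold and 3-fold above the mean, 4% and 87% of them were called. So few raised windows make the adjusted limit stricter than in the measured libraries, where 28 reads were enough for a call. These 2 shares therefore do not give the sensitivity of the calls made here. A chromosome 11 made higher by 0.58 (log2) in line 2 over line 3 was measured at 0.585, and one left equal in line 1 and line 3 at -0.045. That error is close in size to the SD over the other autosomes in the measured data for that contrast (0.05). It exceeded the largest error of any other autosome in the simulation, which was 0.0234. Alternatives covered window size, read counting, fragment length, pseudocounts, thresholds, scaling and leaving out each line. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.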

Results

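DNA methylation and RNA were profiled in 3 mouse EpiSC lines, 1 MethylCap library and 1 RNA library per line. Each MethylCap library held 7139891 mapped reads and each RNA library 44903007. The 5-kb windows with a MethylCap read in any line numbered 502265, with a mean of 14.1 to 14.2 reads per window and library. At that depth a window needed 28 reads to be called methylated in each line. The series title sets EpiSCs against embryonic stem cells; only EpiSC libraries were analysed here, so the comparisons below describe what the 3 lines share and where they differ. Coordinates are those of mm9, and no annotation of that build was used. There was 1 library per line and assay, so no value of a single line has a replicate.

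The first question was how much of the captured methylome the 3 lines share. The lines held 67360, 54769 and 54794 methylated windows in lines 1, 2 and 3, which were 13.4%, 10.9% and 10.9% of the windows. All 3 lines shared 32472 methylated windows (6.47%), 40.5 times the 801 expected from independent calls. Capture also depends on CpG density, which is common to the lines, so that excess alone does not show shared methylation. Chromosome 11 had the highest share of windows methylated in all 3 lines, 18.8%, against 3.57% on chromosome 3, the lowest among autosomes. On the X chromosome 51 of 30103 windows (0.169%) were methylated in all 3 lines, and line 2 had more methylated X windows (1.54%) than line 1 (0.578%) or line 3 (0.206%). The call is set against the mean of the whole library, so these shares also depend on chromosome copy number, which was not measured. The windows methylated in 1 line only numbered 15421 in line 1, 9558 in line 2 and 8554 in line 3.

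The window with the strongest capture was chromosome 17:39980001-39985000, with 780 ± 213 RPM (SD, n = 3 lines). Its neighbour at 17:39985001-39990000 had 152 ± 39.4 RPM, and neither had an RNA read in any line. Mappability was not checked for any window here, so the counts of the leading windows are not shown to come from single-copy sequence. For the same reason, a lack of RNA reads in them does not show a lack of transcription. The other leading windows were 11:3090001-3095000 (185 ± 40.7 RPM), 2:98500001-98505000 (126 ± 22.6 RPM) and 11:3050001-3055000 (121 ± 30.3 RPM). Line 1 had the most RPM of the 3 lines in 4 of these 5 windows; at 2:98500001 line 3 had 139.2 RPM and line 1 138.3. Signal per window was more uneven in line 1, with a median of 7 reads against 11 in lines 2 and 3. The 0.1% of windows with the most reads started at 246 reads in line 1, 101 in line 2 and 119 in line 3. Between pairs of lines, Spearman's rho across windows was 0.785 ± 0.010 (SD of 3 pairs) and Pearson's r 0.763 ± 0.001. The agreement depended on window size: the mean rho was 0.461 with 1-kb windows.

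RNA was compared between the lines in the same windows. Of 238564 windows with an RNA read in any line, 48634 had at least 1 RPM in all 3 lines, and these held 97.9%, 97.2% and 96.6% of the reads of lines 1, 2 and 3. The leading window, 17:45705001-45710000, had 4335 ± 165 RPM (SD, n = 3). It was followed by 17:35970001-35975000 (2494 ± 269 RPM), 11:48615001-48620000 (2116 ± 290 RPM) and 2 adjacent windows on chromosome 19. These were 19:44375001-44380000 (2009 ± 263 RPM) and 19:44380001-44385000 (1967 ± 310 RPM). The 100 windows with the most reads held 9.30%, 8.50% and 7.84% of the reads. Pairs of lines had a mean rho of 0.839 ± 0.011 and r of 0.989 ± 0.004 (SD of 3 pairs) across windows. Windows with an RNA read numbered 142140 in line 1, 163438 in line 2 and 209339 in line 3. Distinct RNA read starts had the same order, 13059280, 16255716 and 18835893 at equal totals. The window numbers are therefore not shown to reflect wider transcription in line 3.

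Both assays were then set against each other within each line. Windows with more RNA had more captured DNA, up to 100 RPM of RNA. Windows without an RNA read were methylated in 4.34 ± 0.716% of cases (SD, n = 3 lines), those above 1 to 10 RPM in 30.5 ± 2.47%, those above 10 to 100 RPM in 40.7 ± 2.76% and those above 100 RPM in 40.2 ± 1.29%. The last 2 classes differed by less than the spread between lines. Mean MethylCap signal was 1.32 ± 0.166 RPM in windows without RNA and 4.54 ± 0.950 RPM in those above 10 to 100 RPM. Spearman's rho across windows was 0.361, 0.401 and 0.421 in lines 1, 2 and 3 (mean 0.394 ± 0.031, SD, n = 3), and windows are not independent replicates. The mean was 0.221 with 1-kb windows and 0.283 in windows with an RNA read. A 5-kb window can hold a promoter and a gene body together, so the values say nothing about promoters alone. CpG density was not controlled for, and capture depends on it. The relation is therefore between RNA and captured DNA, and is not shown to be one with methylation level.

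**Figure D1:**
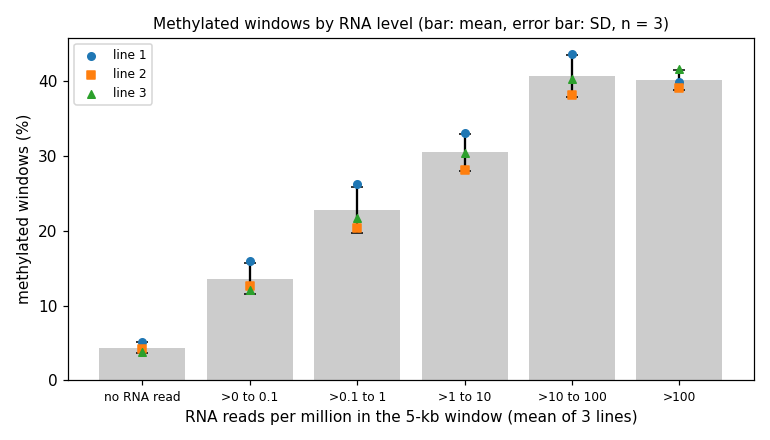
Share of 5-kb windows called methylated (vertical axis, %) by the RNA level of the window (horizontal axis, RPM, mean of 3 lines). Bars are means over the 3 lines, error bars are SDs and symbols are single lines. The mean was 4.34% in windows without RNA and 40.7% in windows above 10 to 100 RPM. CpG density was not controlled for.

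The line number allowed a test of whether a line with more methylation in a window had less of its RNA. Over 98597 windows that were expressed or methylated, the mean correlation between the deviations of the 2 assays was -0.0865 with each line paired with itself. Of the 6 possible pairings of libraries, 2 gave a value as low or lower (exact permutation test, one-sided p = 0.333), and the smallest p this design can give is 0.167. The other pairings gave values from -0.105 to 0.0714. The sign changed to 0.0366 when all windows with reads in both assays were used.

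On the log2(RPM + 0.1) scale, MethylCap windows that lay at least 4-fold above or below both other lines numbered 1279 of the 159286 with enough reads. The scale sets a line with 0 reads lower than the floor of 3 reads used for the named regions. The fold given for a named region can therefore be under 4-fold. Line 2 was higher in 219 windows, and 166 of these (75.8%) were on the X chromosome. Line 1 was higher in 24 windows and lower in 902, where it had a median of 2 reads. Line 3 was higher in 31 windows and lower in 76, of which 25 were on X. The counts depended on how low windows were treated: with a pseudocount of 1 RPM, 62 windows passed, 41 of them X windows higher in line 2 and 1 lower in line 1. With at least 40 reads in the highest line, 148 passed, 88 of them X windows higher in line 2 and 0 lower in line 1. Compared with 1 other line only, a looser rule, line 2 was higher in 301 X windows without line 1 and in 283 without line 3, and 738, 2392 and 2738 windows differed in all without lines 1, 2 and 3.

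Of the 5 regions that differed most in line 2, 3 were X windows with more reads in that line. X:54645001-54650000 had 46 reads in line 2 and 2 in each of the other lines, a ratio of 23 with a 95% counting interval of 6.02 to 196. X:136595001-136600000 had 104 reads in line 2 against 7 and 6 in lines 1 and 3 (ratio to line 1 14.9, interval 6.96 to 37.9). X:20000001-20005000 had 69 reads against 5 and 5 (ratio 13.8, interval 5.64 to 43.8). On an autosome, 17:4625001-4630000 had 86 reads in line 2 against 5 and 3 (ratio to line 1 17.2, interval 7.09 to 54.3). The fifth region, Y:30001-35000, had 0 reads in line 2 against 15 and 20, and was 5-fold lower with the floor of 3 reads.

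Among the 5 regions that differed most in line 3, of 106, 7:37480001-37485000 had the most reads, with 5 in line 3 against 246 in line 1 and 100 in line 2 (ratio of line 2 to line 3 20, interval 8.29 to 62.9). Lower X regions were also found in line 3. X:11240001-11245000 had 0 reads there against 11 and 30 in lines 1 and 2, X:55290001-55295000 had 0 against 10 and 52, and X:68300001-68310000 had 1 against 15 and 56. With the floor of 3 reads, the first 2 were 3.67-fold and 3.33-fold lower than in line 1. At 1:121670001-121675000 line 3 had 20 reads and the other lines 0, 6.67-fold higher with that floor. Windows lower in line 1 numbered 1 with a pseudocount of 1 RPM and 0 with at least 40 reads in the highest line. Signal was also more uneven in line 1, so its lower regions are not shown to be local losses. The 5 regions that differed most in line 1 all had 0 reads there. They were 6:17020001-17025000, 6:94865001-94870000, 12:12715001-12720000, 3:107520001-107525000 and 13:47695001-47700000, with 16 to 26 reads in the other lines. With the floor of 3 reads they were 5.33-fold to 5.67-fold lower than in the nearer line.

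RNA differed by the same rule in 41 of 20298 windows. On the log2(RPM + 1) scale, which understates folds of low windows, the largest difference from the nearer line was at X:100655001-100680000. These 5 adjacent windows had 866 RPM in line 2, 26.1 in line 1 and 1.65 in line 3. Line 2 was lower in 14 windows, of which 11 were on Y and 3 were adjacent on X. Y:595001-605000 had 8.15 RPM in line 2 against 222 and 200 in lines 1 and 3, and Y:345001-370000 had 5.23 against 146 and 136. X:72630001-72645000 had 9.42 RPM in line 2 against 112 and 97.3. In line 1, 10:24315001-24320000 had 5.46 RPM against 75.6 and 114 in lines 2 and 3, and 5:23205001-23215000 had 2.45 against 39.1 and 56.2. In line 3, 16:36750001-36755000 had 0.0445 RPM against 19.6 and 19.5, and 2:98500001-98510000 had 35.2 against 0.824 and 0.267; the latter region holds 1 of the most captured windows, and its mappability was not checked. Of the 7 autosomal windows lower in RNA in line 1, 1 also differed by the MethylCap rule in that line. With 2-fold and 8-fold limits, 254 and 21 windows differed.

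Read shares of the sex chromosomes were compared between lines and assays; the labels do not give the sex of the lines. The X chromosome took 3.10% of MethylCap reads in line 2 (Wilson 95% interval 3.09 to 3.12), 1.36% in line 1 (1.35 to 1.37) and 1.81% in line 3 (1.80 to 1.82). The share of line 2 was 1.96 times the mean of the other lines. Of RNA reads, X took 3.76%, 3.72% and 3.75% in lines 1, 2 and 3, and line 2 had 0.991 times the mean of the others. MethylCap reads on Y numbered 69 in line 2, 875 in line 1 and 1485 in line 3. RNA reads on Y numbered 934 in line 2, 23597 in line 1 and 24380 in line 3. Line 2 had the fewest Y reads in both assays.

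Among autosomes, chromosome 11 stood apart, a comparison chosen after the values were seen. It took 9.735%, 8.570% and 6.807% of MethylCap reads in lines 1, 2 and 3, and 12.6%, 11.6% and 10.6% of RNA reads. After matching windows on signal, chromosome 11 was 1.36-fold higher in line 2 than in line 3 (log2 0.44), while the other 18 autosomes had an SD of 0.01 and reached at most 0.02. Line 1 was 1.19-fold higher than line 3 (log2 0.25; other autosomes SD 0.05, highest 0.13). RNA of chromosome 11 was 1.10-fold higher in line 2 than in line 3 (log2 0.14; other autosomes SD 0.03, highest 0.04) and 1.16-fold higher in line 1 (log2 0.21; SD 0.03, highest 0.06). In 2-Mb bins, 59 of 59 bins of chromosome 11 were above the median autosome in line 2 over line 3, and 58 were above the 95th percentile of the other autosomal bins. In line 1 over line 3, 54 of 59 were above the median autosome and 22 above that percentile, with a lowest bin of -0.43 (log2).

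**Figure D2:**
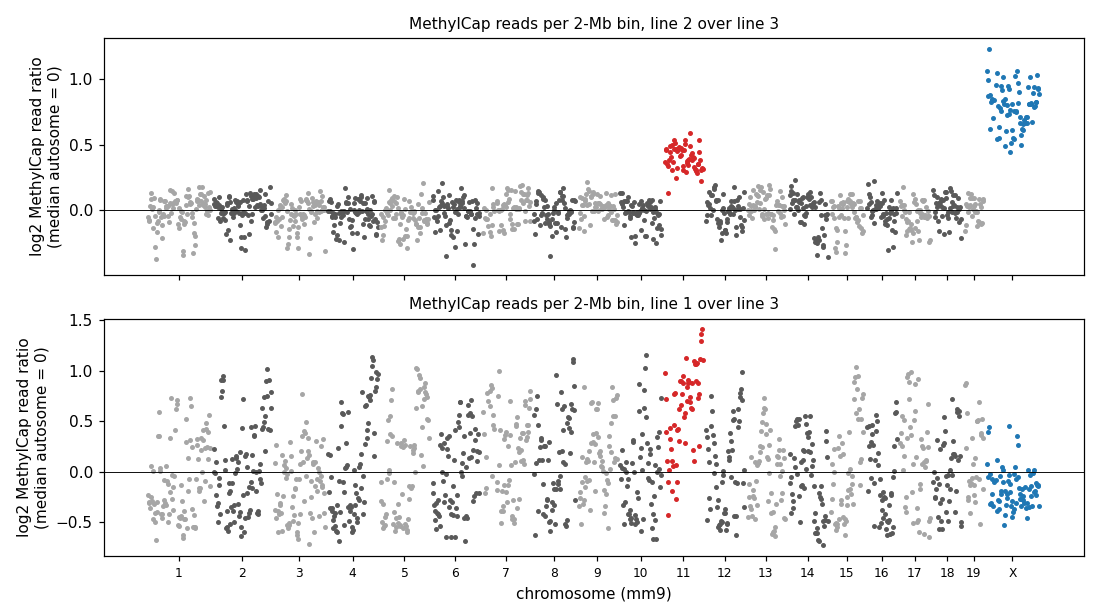
MethylCap read ratio (vertical axis, log2, median autosome at 0) in 2-Mb bins along the chromosomes (horizontal axis, mm9), for line 2 over line 3 (upper) and line 1 over line 3 (lower). Each point is a bin, with chromosome 11 in red and X in blue. In the upper panel 59 of 59 bins of chromosome 11 and 76 of 76 X bins lie above 0. In the lower panel 54 of 59 bins of chromosome 11 do, 22 of them above the 95th percentile of the other autosomal bins, and that panel has a wider spread, with an SD of 0.43 over the other autosomal bins against 0.11 in the upper one.

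**Figure D3:**
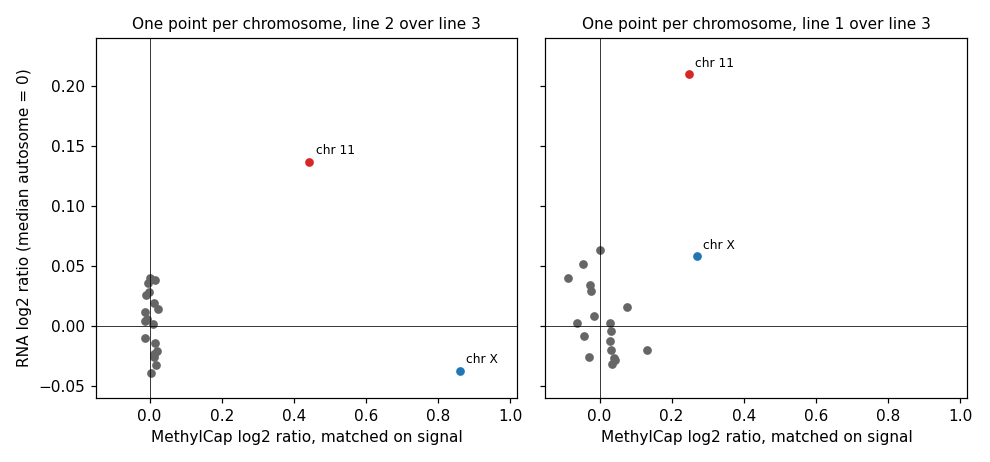
Chromosome-wide MethylCap ratio after matching windows on signal (horizontal axis, log2) against the median RNA ratio (vertical axis, log2), for line 2 over line 3 (left) and line 1 over line 3 (right). Each point is a chromosome. Chromosome 11 (red) was higher in both assays, at 0.44 and 0.14 on the left; X (blue) was at 0.86 for MethylCap and -0.04 for RNA on the left.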

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

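All tests of explanations in this part were chosen after the results were seen, and each pattern rests on 1 library per line. The 2 values given here come from the unexplained 0 or 1 column of the MethylCap files, which no comparison used; each stood out as over 1.5 times the share in both other lines. The value was 1 for 17.9% of the reads of line 3 (Wilson 95% interval 17.89 to 17.95), against 7.53% in line 1 and 7.58% in line 2. Among Y reads it was 1 for 75.3% in line 2 (55 of 73 reads, interval 64.4 to 83.8), against 10.7% in line 1 and 17.6% in line 3.

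The first pattern is the high chromosome 11 signal of lines 1 and 2 relative to line 3. A stronger capture of densely methylated DNA in 1 library is argued against for line 2, whose chromosome 11 remained 0.421 (log2) above the highest other autosome after matching on signal (SD over those autosomes 0.01), and so is a gain limited to strongly methylated windows, since the windows with the lower signal gave 0.330. For line 1 the excess was 0.115 and capture stays open, because the same matching put X of line 1 over line 3 at 0.27 where plain shares gave -0.37. Extra copies of chromosome 11 in part of the cells would raise RNA too. In both lines chromosome 11 RNA exceeded every other autosome relative to line 3, by at least 0.0964, which makes extra copies a candidate explanation. Line 3 is the reference in both comparisons, so the 2 are not independent. They cannot tell a higher chromosome 11 in lines 1 and 2 from a lower one in line 3. The order of lines 1 and 2 depended on the measure, however: line 2 over line 1 was 0.20 in matched MethylCap, -0.18 in plain MethylCap shares and -0.07 in RNA, the passages of the assays differ, and a methylation change along the whole chromosome was not tested apart from copy number.

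The second pattern is the set of 166 X windows at least 4-fold higher in line 2. A general difference of capture between libraries is argued against, because autosomal windows with the same number of line 2 reads, at least 20 on both sides, gave an expected 0.595 windows, and the observed number was 279 times that. A second X with the same methylation per copy is argued against as the whole cause. The same autosomal windows, with lines 1 and 3 thinned to 1 copy, gave an expected 29.1 windows. The observed number was 5.70 times that. Both matches used line 2 counts alone. At least 20 line 2 reads were reached by 1147 of 30103 X windows, a smaller share than among autosomal windows (121705 of the 502265 windows in all). Stricter selection on line 2 can make both expected numbers too low, by an amount not measured. The X share of RNA in line 2 was 0.991 times that of the other lines, where a transcribed second X would raise it. The 166 windows were 13.6% of the 1220 X windows with enough reads. Over the whole chromosome X was 1.82-fold higher in line 2 than in line 3 and 1.51-fold higher than in line 1, matched on signal. On plain shares the values were 1.76-fold and 2.28-fold. These values do not settle whether a second X carries more methylation as a whole. A second, mostly silent X with more methylation in part of its windows stays a candidate. Line 2 also had the fewest Y reads in both assays, which does not count X copies. RNA was at least 4-fold higher in line 2 than in both other lines in 5 windows, all at X:100655001-100680000. This region had 866 RPM in line 2 against 26.1 and 1.65 in lines 1 and 3. The gene there was not identified, so its RNA was not used as a test. Sex and copy number were not given by the labels, and the hypothesis has no independent test here.

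The third pattern is a small remainder of RNA where another line has much more. Line 1 had 3.02% of the line 2 level over X:100655001-100680000 and line 3 had 0.190%, while line 2 had a median of 3.78% of the Y level of lines 1 and 3. Reads of X origin placed on Y in line 2 are argued against, since the share varied only 1.46-fold over 10 Y windows (3.36% to 4.90%). Mixing between the RNA of lines 1 and 2, in the tube or in culture, stays open: outside that X region and Y, 0 windows of at least 10 RPM in either of these lines fell under 2% in the other, but line 3 itself had 1 such window against each (16:36750001-36755000). Lines 1 and 2 had 1 and 2 such windows against line 3, all in 2:98500001-98510000, and these 3 different windows in 2 regions are too few for the count to decide. Low transcription of the X region in line 1 itself stays open, as the share over its windows varied 1.57-fold, which either explanation allows.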

How the results depend on the processing

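Of 102 alternative values, 58 were counted as unchanged, 43 moved further and 1 changed sign. Unchanged meant within the spread between replicates (for chromosome 11, the SD over the other autosomes), or within 1.5 times for counts. For the value with each line paired with itself only the sign was compared, so -0.0262 against -0.0865 counts as unchanged. The causes were not tested. Common distributions, 1-kb windows for the relation of the assays, removal of chromosomes 11, X or Y, single counting of RNA starts for the windows that differ, leaving out a line for the X shares, the floor of 3 reads, the X and line 1 counts and every chromosome 11 setting were chosen after seeing the data. Promoter, CpG content and gene background settings and both marker list results were not run, for want of an mm9 annotation.

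MethylCap rho (0.785) and r (0.763) were 0.461 and 0.485 with 1-kb windows, 0.908 and 0.895 with 20-kb windows, and 0.748 and 0.725 with at least 10 reads; r was 0.817 with a pseudocount of 1. Without 1 line they ranged from 0.774 to 0.795 and from 0.762 to 0.765. RNA rho (0.839) and r (0.989) were 0.959 and 0.975 in windows of at least 1 RPM, and r was 0.981 with a pseudocount of 0.1; without 1 line they ranged from 0.829 to 0.852 and from 0.984 to 0.991. Shared methylated windows (32472) were 18187 at an adjusted p under 0.0001, and expressed windows (48634) were 31724 at 3 RPM. The methylation to RNA rho (0.394) was 0.283 in windows with an RNA read and 0.221 with 1-kb windows.

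The same-line pairing value of -0.0865 turned to 0.0366 with all windows that had reads in both assays; the replicate block, deviations pooled over windows for the same-line pairing alone, gave -0.0262. No call changed, as the exact p cannot fall below 0.167.

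Differing MethylCap windows (1279), X windows higher in line 2 (166) and windows lower in line 1 (902) numbered 62, 41 and 1 with a pseudocount of 1, and 148, 88 and 0 with at least 40 reads. With 1 common distribution the first and last were 702 and 178, and with 1-kb windows the last was 10; with no pseudocount and counts under 3 reads set to 3, they were 1575, 187 and 1067. Compared with 1 other line only, they ranged from 738 to 2738, 283 to 301 and 2088 to 2446; 738 was without line 1, where a looser rule still gave fewer windows. RNA windows (41) numbered 70 at 3 RPM, 254 at 2-fold and 21 at 8-fold.

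The X share of RNA in line 2 relative to the others (0.991) was 0.987 with starts counted once and 0.957 without the 1% of windows with the most reads. Chromosome 11 in line 1 over line 3 (0.247) was 0.549 on plain shares. In line 2 over line 3 (0.443) it was 0.368 on plain shares, 0.426 with 10 bins and 0.330 in the lower-signal windows. Depth let 159286 of the 502265 MethylCap windows enter the comparison of single windows, since the others had fewer than 20 reads in each line.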

Other observations

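All tests in this part, and the choice of values to set together, were made after the results were seen. The X share of MethylCap reads and the naming of the most captured windows were planned. The X windows higher in line 2 lay in windows with and without 1 RPM of RNA. Of X windows with at least 20 MethylCap reads in a line, 85 of the 462 with a mean of at least 1 RNA RPM (18.4%) and 10.7% of the others were at least 4-fold higher in line 2. Their median MethylCap reads were 6, 41 and 4 in lines 1, 2 and 3. RNA of the 85 windows in line 2 had a median log2 ratio to the other lines of -0.09. This was at percentile 32.1 of the medians of 10000 random lists of other X windows, of the same size and matched on mean RNA level, a description of these libraries only.

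X:72630001-72645000 was the 1 X region whose RNA was at least 4-fold lower in line 2 than in both other lines, with at least 10 RPM in the highest line. It had 9.42 RPM against 112 and 97.3, and 31 MethylCap reads in line 2 against 8 and 16. The X share of MethylCap reads as a whole was 1.96 times the mean of the other lines in line 2, so a rise of that kind is not particular to this region. On an autosome, 10:24315001-24320000 had 5.46 RNA RPM and 184 MethylCap reads in line 1, against 75.6 and 114 RPM and 28 and 40 reads in lines 2 and 3. At 5:23205001-23215000 line 1 had 2.45 RPM and 169 MethylCap reads, against 39.1 and 56.2 RPM and 66 and 92 reads.

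These regions raised the hypothesis that windows with lower RNA in line 1 gained methylation there. MethylCap was highest in line 1 in 5 of the 7 autosomal windows with lower RNA in that line (71.4%). Among 19520 autosomal windows of at least 10 RPM the share was 44.5%. The 2 regions that raised the hypothesis supply 3 of the 7. Among the other 4, MethylCap was highest in line 1 in 2 (exact binomial test, one-sided p = 0.600), so the hypothesis has no support apart from those regions, and 4 windows are too few to exclude it.

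The region 2:98500001-98510000, among the most captured in all 3 lines (1759, 1284 and 1774 MethylCap reads), had 35.2 RNA RPM in line 3 against 0.824 and 0.267 in lines 1 and 2. The most captured window, 17:39980001-39985000, had no RNA read in any line. Mappability of these windows was not checked, so the lack of RNA reads there does not show a lack of transcription.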
